A study of Mus musculus with 6 samples.

How the data were processed

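Epidermis of WT and AhRCA mice at postnatal day 0 was profiled on 6 Agilent 1-colour arrays, 3 per genotype. Per the labels, RNA was extracted with an RNeasy Micro kit and labelled with Cy3 by the Quick Amp method, and each sampling paired 1 AhRCA mouse with 1 WT littermate; separate animals are therefore the replicates. Per the file headers, the scanner values are spot intensities from Agilent Feature Extraction 10.7.3.1, which subtracted the local background and removed spatial trends on each array, without scaling between arrays. Each array had 45018 spots, 1639 of them controls. The deposited table of the authors holds log2 values for 41267 probes in 6 columns. Differences between arrays in it equalled those of the log2 processed intensity plus 1 constant per array, with a slope of 1.0, so that its scale is log2, each array was scaled near its 75th percentile and each probe was centred on its median over the 6 arrays. Its direction is that of the intensities, and its column medians were -0.0703, -0.0494 and 0.0825 for WT 1 to 3 and 0.0282, 0.0633 and -0.0704 for AhRCA 1 to 3.

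Values were log2 processed intensity minus each array's 75th percentile over non-control spots. Control spots and between 56 and 94 spots per array marked as outliers were left out, and replicate spots of a probe (10 for each of 245 probes) were averaged. The 75th percentile of the signal was between 627 and 754 and the median between 50.5 and 69.3; the number of arrays limits the precision. The files held no gene symbols, so the fits, planned on symbols, used symbols obtained from unversioned RefSeq accessions through a table of the GRCm38.p6 assembly; no coordinates were used. Of 41174 probes 26690 matched 1 symbol, 0 several and 14484 none, which named 18217 genes, 6474 of them by more than 1 probe. Probes well above background on at least 3 of the 6 arrays were kept, 24005 in all and 18648 of them named, and the probe with the highest mean over all arrays stood for its gene. This left 12824 genes, 3 of them with a value missing on 1 or more arrays. Among called genes with more than 1 kept probe, 0 of 50 had probes that disagreed in sign.

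The genotypes were compared with limma (lmFit and eBayes, 2 group means, prior degrees of freedom 2.625), with two-sided tests, Benjamini-Hochberg adjustment and a threshold of 0.05. A gene not well above background on any array of a group, in any of its probes, has only a bound. It was computed from the brighter group's mean and, for the dimmer group, the mean of the higher of each array's lowest well-above-background signal and the probe's own value, all on the normalized log2 scale, and is given as at least N-fold. There were 8 called genes of this kind in WT and 34 in AhRCA. Slides and scans coincided, and the fits with the slide as a block and within slide 1 are given beside the counts.

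Before the data were examined, 36 gene lists with 561 entries were fixed, of which 517 are on the array: AhR targets, AhR complex, antioxidant response, neurotrophic and axon guidance factors, alarmins and interleukins, chemokines, antimicrobial proteins, basal and spinous keratinocytes, cornified envelope, late cornified envelope and small proline-rich genes, barrier lipid synthesis, proteases and inhibitors of desquamation, wound-type keratinocyte genes, cell cycle, EGF receptor ligands, tight junctions and desmosomes, retinoid metabolism, interferon-stimulated genes, circadian clock, immediate early and heat shock genes, hair follicle, sebaceous gland, Langerhans and dendritic cells, T cells, mast cells and basophils, neutrophils, melanocytes, fibroblasts, endothelium, skeletal muscle, Schwann cells and nerve, erythroid cells, adipocytes, Merkel cells and sex-linked genes. The 32 lists with at least 3 tested members were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives.

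The rule for named genes was fixed at the same time. It takes Ahr, Artn, Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Tiparp, Tslp and Il33 whatever their result, and the 10 largest rises and 10 largest falls among called genes well above background on all 6 arrays whose groups do not overlap. It adds up to 5 called genes in each direction that were measured in 1 genotype only, and up to 4 called members of each list, or the 2 with the largest change where none was called.

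Whether replicate numbers pair the samples was decided from the labels' littermate samplings and from the correlation of deviations from the group means across 12821 genes, before calls were compared. Same-numbered arrays correlated at 0.337, 0.372 and 0.55, and other pairs of arrays between -0.416 and 0.194, so the pairing was accepted. The 0.55 and the negative values involve the arrays of slide 2, where litter and slide cannot be told apart. Within slide 1 same-numbered arrays had 0.337 and 0.372 and the others 0.194 and 0.15. The fit without the block remained the one reported, as planned.

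Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes, a filter of all 6 arrays, the mean of a gene's probes, an intensity trend with a robust prior, array weights, the replicate block, the slide block, the authors' log2 values, an adjusted p under 0.1, a fold of at least 2, and each array left out in turn. The files lack the mean signal planned for normexp, and the median spot and background signals were used. Slide 1 alone, probes with no symbol as features of their own, and an estimated correlation with the replicate block were chosen after seeing the data.

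The fit was tested on simulated data over 12821 genes for AhRCA against WT in 20 runs with 200 changed genes each. It called 3.96% of genes changed by 0.5 on the log2 scale, 68.1% of those changed by 1 and 95.9% of those changed by 2, and 0.0512% of unchanged genes, and 5.46% of its calls were unchanged genes. Camera called a list raised by 0.5 in 20 of 20 runs and made 0 calls of other lists. The simulated genes varied independently of one another and without a slide effect. The list calls in these runs therefore do not measure camera's error where genes of a list are correlated. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Probes without a symbol were left out of the gene counts.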

Results

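Gene expression was measured in the epidermis of newborn mice of 2 genotypes. The 3 AhRCA samples carried a constitutively active form of the aryl hydrocarbon receptor (AhR), a transcription factor that responds to dioxins and other xenobiotics, expressed from the promoter of keratin 14, a keratin of basal keratinocytes. The 3 wild-type (WT) samples came from littermates. Each sample was hybridized to its own 1-colour Agilent array. Between 56.2% and 61.3% of the spots of an array were well above background, and 0 spots were saturated; the number of arrays, 3 per group, limited the precision. Replicates 1 and 2 of both genotypes lay on slide 1 and replicate 3 of both on slide 2. The principal component with the largest share of variance (37.8%) separated the genotypes, and the next (35.5%) separated the slides. The brightest Xist probe, which reads the transcript of the inactive X chromosome, stood at log2 intensities of 4.43, 4.44, 4.66 and 4.57 in WT 1, WT 2, AhRCA 1 and AhRCA 2, and at -4.20 and -7.14 in WT 3 and AhRCA 3. The brightest probes of Ddx3y, Eif2s3y and Kdm5d, genes of the Y chromosome, stood at 1.65, 2.61 and -1.105 in WT 3. They stood at 1.43, 2.40 and -0.88 in AhRCA 3, and between -7.29 and -6.34 on the arrays of slide 1. By these transcripts the mice of pair 3 were male and those of pairs 1 and 2 female. Slide, litter pair 3 and sex therefore coincided, and each was balanced between the genotypes.

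The comparison of AhRCA with WT asks which transcripts of newborn epidermis differ when AhR is constitutively active in keratinocytes. In AhRCA epidermis the xenobiotic-metabolizing enzymes Cyp1a1 and Cyp1b1 and the AhR repressor Ahrr stood 135-fold, 40.6-fold and 60.2-fold above WT. Artn, which encodes artemin, a factor that supports sensory neurons, stood 6.72-fold above WT. Lower in AhRCA were Elovl3, an elongase of very long chain fatty acids (11.8-fold), Soat1, which esterifies cholesterol (5.05-fold), and Krt20, a keratin of Merkel cells (6.12-fold). The keratins of the basal and spinous layers, Krt5, Krt14, Krt1 and Krt10, chosen after their values were seen, had log2 fold changes between -0.05 and 0.02, each with an adjusted p of 0.999 (limma, Benjamini-Hochberg).

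Of 12824 genes tested, 279 (2.18%) changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 68 of them higher in AhRCA and 211 lower, so that 75.6% of the changed genes were lower. A change of at least 2-fold was found in 41 of the higher and 168 of the lower genes. With the litter pair as a block 497 genes changed (137 higher, 360 lower), with the slide as a block 539 (166 higher, 373 lower), and on slide 1 alone 130 (35 higher, 95 lower). The count was 62 without WT replicate 2, 71 without AhRCA replicate 2, 104 without AhRCA replicate 1, 151 without AhRCA replicate 3 and 185 without WT replicate 3. Fold changes of pair 3 on slide 2 and of the pairs on slide 1 correlated across 12822 genes with r = 0.521 and rho = 0.272, where genes are not independent replicates.

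Of 12 tested members of the list of known AhR target genes, 6 rose and 0 fell, and 8 rose when adjusted over the list alone. Cyp1a1 rose by a log2 fold change of 7.07 ± 0.58 (SE, n = 3 per group), from a normalized log2 intensity of -3.06 ± 0.89 (SD) in WT to 4.02 ± 0.91 in AhRCA, with an adjusted p of 0.00470 (limma, Benjamini-Hochberg). Ahrr, which competes with AhR for its partner, rose by 5.91 ± 0.35 (adjusted p = 0.00164) and was well above background on 2 of 3 WT arrays. Cyp1b1 rose by 5.34 ± 0.14 (adjusted p = 5.62e-05), Nqo1, a quinone reductase, by 2.13 ± 0.19 (adjusted p = 0.00546) and Tiparp, an ADP-ribosyltransferase that dampens AhR signalling, by 1.45 ± 0.10 (adjusted p = 0.00236). With normexp background correction the log2 fold changes of Cyp1a1, Cyp1b1 and Ahrr were 6.24, 4.87 and 4.30. The list stood above the other genes (camera, adjusted p = 3.97e-14). It was the only 1 of 7 called lists to keep its call with an estimated correlation (adjusted p = 0.0439). It lost that call when the litter pair was added as a block (adjusted p = 0.574), a setting in which 0 lists passed. Its median log2 fold change was 1.05 on slide 1 and 0.89 on slide 2. Neither of the probes of Cyp1a2 was well above background on any array.

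**Figure D1:**
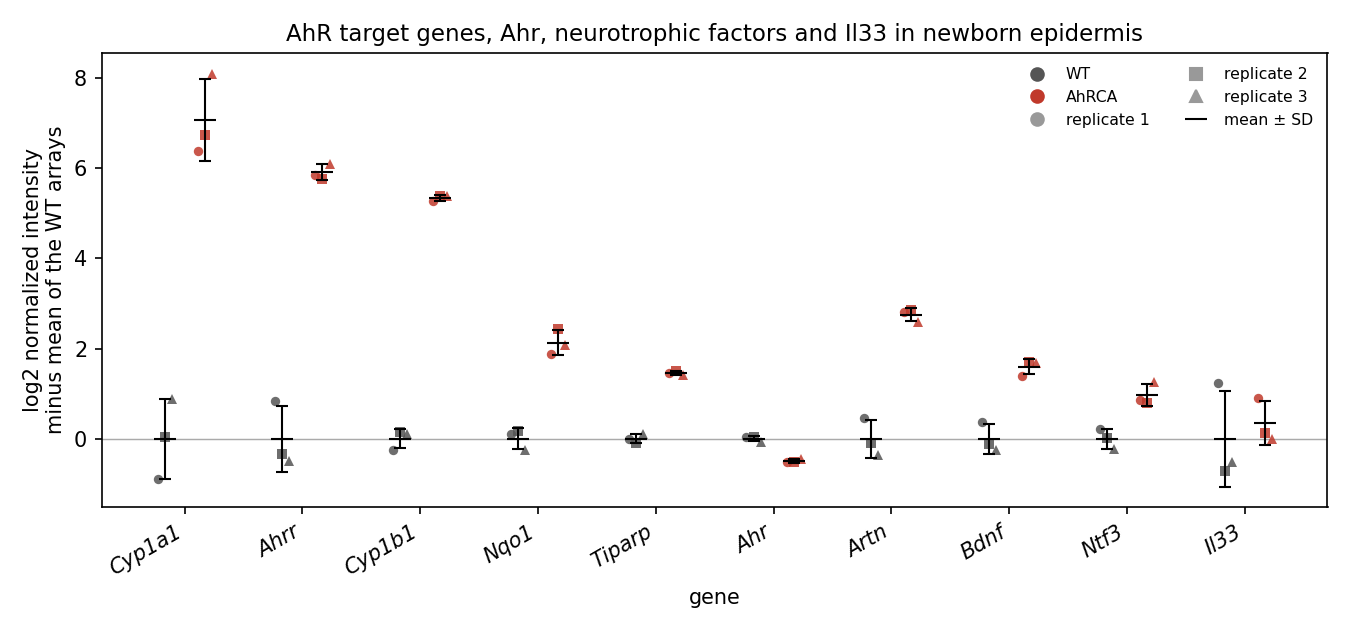
Log2 normalized intensity of 10 genes on each array, minus the mean of the 3 WT arrays of that gene (vertical axis, log2 units). Grey symbols are WT and red symbols AhRCA, shapes mark the replicate number, and black marks give the mean ± SD of 3 arrays. The AhRCA means of Cyp1a1, Ahrr and Cyp1b1 lie 7.07, 5.91 and 5.34 above WT, that of Artn lies 2.75 above and that of Ahr at -0.49, while the Il33 arrays of the 2 genotypes overlap.

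The Ahr transcript itself had a log2 fold change of -0.49 ± 0.10 in AhRCA and missed the threshold (adjusted p = 0.0653, limma, Benjamini-Hochberg). It passed with the slide as a block (adjusted p = 0.0331) and not with the litter pair (adjusted p = 0.0636), and was lower on 3 of 3 AhRCA arrays than on any WT array. Whether its single probe reads the transgene was not known here, so the value checks nothing about the labels. Of 9 tested members of the AhR complex list, which holds Ahr, its partner Arnt and its chaperones, 0 passed with limma, 1 had an unadjusted p under 0.05 and 1 fell when adjusted over the list alone (camera, adjusted p = 0.381). Hsp90aa1 had a log2 fold change of -0.12 ± 0.21. Of 20 antioxidant response genes, 2 rose and 0 fell, 3 rose and 1 fell when adjusted over the list alone, and with the litter pair as a block 4 rose and 1 fell. They were Nqo1 and Osgin1, an oxidative stress-induced growth inhibitor, with 1.46 ± 0.20 (adjusted p = 0.0220). Osgin1 lost its call without any 1 array except AhRCA replicate 3 (adjusted p up to 0.103 without AhRCA replicate 2). The list's median was 0.01 (camera, adjusted p = 0.139).

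Among neurotrophic factors, Artn, Bdnf and Ntf3 rose in AhRCA epidermis. Artn rose by a log2 fold change of 2.75 ± 0.22 (adjusted p = 0.00443, limma, Benjamini-Hochberg), from -2.91 ± 0.42 (SD, n = 3) in WT to -0.16 ± 0.15 in AhRCA. Bdnf, brain-derived neurotrophic factor, rose by 1.6 ± 0.19 (adjusted p = 0.0139), and Ntf3, neurotrophin 3, by 0.97 ± 0.17 (adjusted p = 0.0480). Sema3e, an axon guidance factor that repels growth cones, fell by 0.94 on the log2 scale (SE 0.14, adjusted p = 0.0248). Of 15 tested neurotrophic and axon guidance factors 3 rose and 1 fell, and 5 rose and 2 fell when adjusted over the list alone, but the list as a whole did not stand apart (camera, adjusted p = 0.0788, 0.00687 without WT replicate 1 and 0.575 with an estimated correlation). Ntf3 lost its call with the litter pair as a block (adjusted p = 0.0770), with the slide as a block (0.0517) and with normexp background correction (0.0619). Artn kept its call whichever array was left out, whereas Bdnf lost it without WT replicate 2 (0.0673), AhRCA replicate 2 (0.0746) or AhRCA replicate 3 (0.0559). Sema3e lost it without any 1 array except WT replicate 1 (up to 0.116) and Ntf3 without any 1 array (up to 0.175).

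Among genes well above background on all 6 arrays, the largest rises outside the AhR targets and Artn were those of Ptgs2, Cyp2j9, Il31ra, Ccno, Lrrk2 and Plcg2. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by a log2 fold change of 2.85 ± 0.44 (adjusted p = 0.0293, limma, Benjamini-Hochberg). Cyp2j9, a cytochrome P450, rose by 2.43 ± 0.15, and Il31ra, a receptor subunit of the itch cytokine interleukin 31, by 2.22 ± 0.18 (adjusted p = 0.00470). Ccno, known from multiciliated cells, rose by 2.22 ± 0.27, the kinase gene Lrrk2 by 1.99 ± 0.36 and Plcg2, a phospholipase of immune receptor signalling, by 1.79 ± 0.11 (adjusted p = 0.00164). Further genes were measured on all 3 AhRCA arrays and not well above background on any WT array. These were Ms4a20 (at least 4.46-fold higher), 1500009L16Rik (at least 4.42-fold), Chst1, a sulfotransferase (at least 3.61-fold), Aoah, which inactivates bacterial lipopolysaccharide (at least 3.55-fold), and Dok5 (at least 2.68-fold), with adjusted p between 0.00164 and 0.0272. Ptgs2 lost its call without any 1 array except WT replicate 1 (adjusted p up to 0.115 without WT replicate 2). The same held for Lrrk2 without any 1 array (up to 0.16) under quantile normalization (0.0630), with the slide as a block (0.0524) and with normexp background correction (log2 fold change 1.08, adjusted p = 0.0506). Dok5 lost its call without any 1 array except WT replicate 2 (up to 0.105) and with normexp background correction (log2 fold change 0.73, adjusted p = 0.0645). Calls were also lost by Ccno without WT replicate 2, AhRCA replicate 1 or AhRCA replicate 2 (up to 0.0618) and Aoah without AhRCA replicate 2 or AhRCA replicate 3 (up to 0.0627).

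Of 9 tested genes of the sebaceous gland 6 fell and 0 rose, 8 fell when adjusted over the list alone and all 9 had negative fold changes. Soat1 fell by 2.34 on the log2 scale (SE 0.16, adjusted p = 0.00196, limma, Benjamini-Hochberg). The values were -2.19 ± 0.19 for Cidea, a lipid droplet protein, -1.85 ± 0.20 for Pparg, a regulator of sebocyte differentiation, and -1.37 ± 0.17 for Scd1, a stearoyl-CoA desaturase, which all fell. The fatty acid synthase gene Fasn, chosen after its value was seen, had -0.07 ± 0.11 (adjusted p = 0.996). The list's median was -1.17, with -1.31 on slide 1 and -1.14 on slide 2. It stood below the other genes (camera, adjusted p = 1.23e-13), but with an estimated correlation the adjusted p was 0.16. With fry it was 0.00548. Pparg lost its call without WT replicate 2 (adjusted p = 0.0504) or AhRCA replicate 2 (0.0610), and Scd1 without WT replicate 2 (0.0638), AhRCA replicate 1 (0.0508) or AhRCA replicate 3 (0.0518). Adipocyte markers, of which 3 were tested and 0 passed (1 at an unadjusted p under 0.05 and 1 adjusted over the list alone), also had negative values, with -0.91 ± 0.46 for Fabp4 and -0.82 ± 0.22 for Lpl. Lpl passed with the litter pair as a block (adjusted p = 0.0225), as did the adipocyte list (camera, adjusted p = 0.0340 with the block, 0.0731 without it and 0.0092 without AhRCA replicate 2). That list also passed with normexp background correction (0.0319), median scaling (0.0360) and the mean of a gene's probes (0.0165). With an estimated correlation its adjusted p was 0.688 with the block and 0.575 without it.

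Of 22 tested genes of epidermal barrier lipid synthesis 3 fell and 0 rose, also when adjusted over the list alone. Fa2h, the fatty acid 2-hydroxylase, was not well above background on any AhRCA array and was at least 25.3-fold lower (adjusted p = 0.00546, limma, Benjamini-Hochberg). Elovl3 fell by 3.57 on the log2 scale (SE 0.30, adjusted p = 0.00497) and Cers4, a ceramide synthase, fell by 1.86 (SE 0.18, adjusted p = 0.00758). The other 19 members did not pass, the list's median was -0.06 (0.06 on slide 1 and -0.33 on slide 2), and the list missed the threshold (camera, adjusted p = 0.0543). It passed under quantile normalization (0.0390), median scaling (0.0332) and normexp background correction (0.00812), with the mean of a gene's probes (0.0466), and without WT replicate 1 (0.00154), WT replicate 2 (0.0264) or AhRCA replicate 1 (0.0114). It did not pass with an estimated correlation (0.575) or with fry (0.198).

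Among the 10 largest falls in genes well above background on every array were also Cyp2g1, a cytochrome P450 (-3.33 ± 0.22, adjusted p = 0.00176, limma, Benjamini-Hochberg), Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase (-2.76 ± 0.29), the kinase gene Wnk4 (-2.74 ± 0.34) and Col9a3, a chain of type IX collagen (-2.44 ± 0.16). Measured on all 3 WT arrays and not well above background on any AhRCA array were Bcan, a proteoglycan (at least 5.20-fold lower), Tgm2, a transglutaminase (at least 5.03-fold), Steap4, a metalloreductase (at least 4.92-fold), and Acoxl (at least 4.47-fold), with adjusted p between 0.000185 and 0.0282. Wnk4 lost its call without WT replicate 2 (adjusted p = 0.0627) or AhRCA replicate 3 (0.0621), and Tgm2 without any 1 array except WT replicate 3 (up to 0.108) under quantile normalization (0.0555) and with normexp background correction (log2 fold change -1.09, adjusted p = 0.0651).

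Hair follicle genes were lower as a list, which had 16 tested members. Lgr5, a marker of follicle stem cells, fell by 0.83 on the log2 scale (SE 0.11, adjusted p = 0.0199, limma, Benjamini-Hochberg), and was the only 1 to pass; 8 fell when adjusted over the list alone and 7 with the litter pair as a block. The median was -0.64, with -0.74 on slide 1 and -0.55 on slide 2 (camera, adjusted p = 0.00132, and adjusted p = 0.575 with an estimated correlation). Among the 10 largest falls of genes well above background on all 6 arrays were Krtap4-2 (-2.49 ± 0.40), Krtap4-16 (-2.44 ± 0.36), Krtap9-3 (-2.38 ± 0.42) and Krtap21-1 (-2.38 ± 0.40), keratin-associated proteins of the hair shaft whose near-identical copies can share a probe. Krtap21-1 lost its call with the litter pair as a block (adjusted p = 0.0622) and Krtap9-3 with the slide as a block (0.0523). Krtap4-2 and Krtap21-1 lost their calls without any 1 array except AhRCA replicate 3 (adjusted p up to 0.141 and 0.132), Krtap9-3 without any except WT replicate 1 (up to 0.141) and Lgr5 without any except WT replicate 3 (up to 0.107). Krtap4-16 lost its call without WT replicate 2, WT replicate 3, AhRCA replicate 1 or AhRCA replicate 2 (up to 0.118). Lgr5 also lost its call under median scaling (adjusted p = 0.0555).

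Merkel cells are touch-sensing cells of the epidermis, and of 5 tested markers 3 fell, 4 when adjusted over the list alone. Krt20 fell by 2.61 on the log2 scale (SE 0.26, adjusted p = 0.00820, limma, Benjamini-Hochberg) and Krt8, a simple epithelial keratin, fell by 2.08 (SE 0.23, adjusted p = 0.0108). Piezo2, a mechanosensitive ion channel, fell (adjusted p = 0.0474), but its tested probe was not well above background on any AhRCA array. Its call was lost with the litter pair as a block (adjusted p = 0.0672) or the slide (0.0596), under quantile normalization (0.0579), with normexp background correction (0.198) and without any 1 array (up to 0.176). Krt8 lost its call without WT replicate 2 (adjusted p = 0.0504). The list stood below the other genes (camera, adjusted p = 4.53e-07). It also did so with probes well above background on all 6 arrays, a setting without Piezo2 (2.41e-06). However, the adjusted p with an estimated correlation was 0.147. With fry it was 0.00618.

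**Figure D2:**
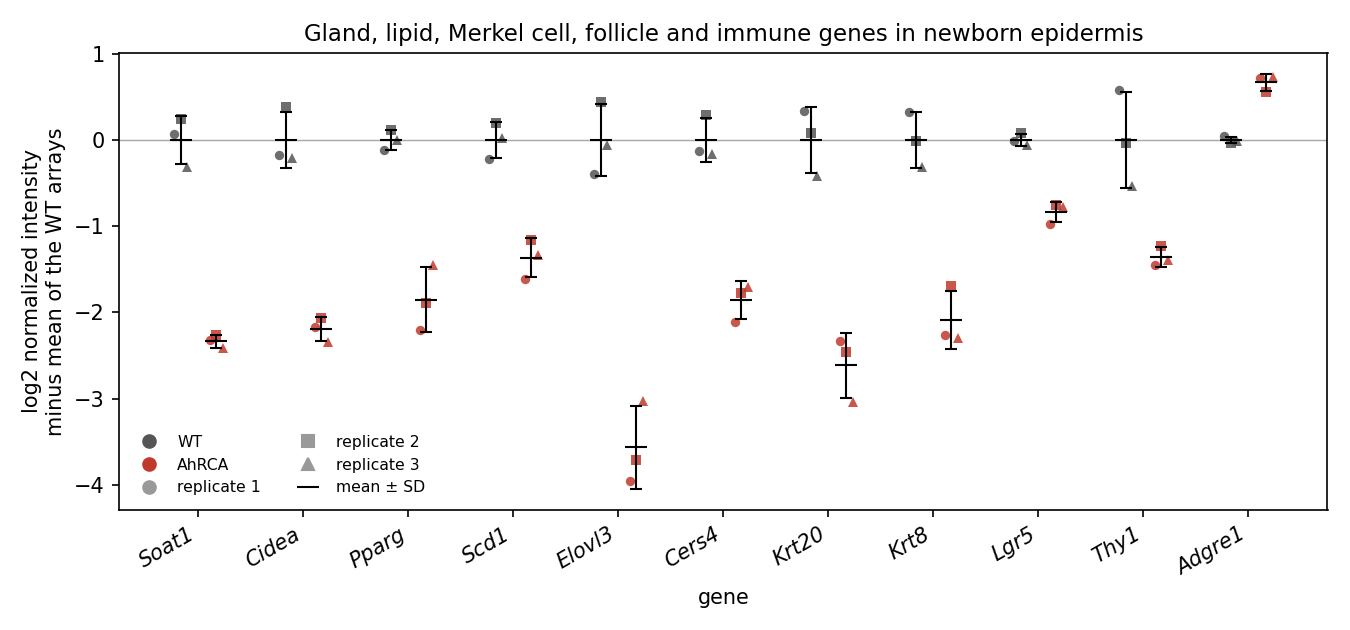
Log2 normalized intensity of 11 genes on each array, minus the mean of the 3 WT arrays of that gene (vertical axis, log2 units). Grey symbols are WT and red symbols AhRCA, shapes mark the replicate number, and black marks give the mean ± SD of 3 arrays. The AhRCA means lie at -3.57 for Elovl3, -2.61 for Krt20, -2.34 for Soat1 and 0.67 for Adgre1, and at -1.36 for Thy1.

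Cd207, which encodes langerin of Langerhans cells, was not well above background on any AhRCA array and was at least 3.09-fold lower (adjusted p = 0.0206, limma, Benjamini-Hochberg). Adgre1, the macrophage and Langerhans cell antigen F4/80, rose by 0.67 ± 0.10 (adjusted p = 0.0321). Of 11 tested Langerhans and dendritic cell genes these were the only 2 to pass, the median was 0.01 and the list did not stand apart (camera, adjusted p = 0.727). With the litter pair as a block 2 rose and 4 fell, and adjusted over the list alone 2 rose and 4 fell. Cd207 lost its call without WT replicate 1, WT replicate 2, AhRCA replicate 1 or AhRCA replicate 2 (adjusted p up to 0.0879), and Adgre1 without any 1 array (up to 0.16) and under median scaling (0.0702). T cell genes stood below the other genes as a list (camera, adjusted p = 0.00545), but not with an estimated correlation (0.575), without AhRCA replicate 2 (0.0529) or with probes well above background on all 6 arrays (0.164). The list had a median of -0.94 over 10 members that was -1.39 on slide 1 and -0.19 on slide 2. None passed alone (0 of 10 with limma, 5 at an unadjusted p under 0.05, 1 adjusted over the list alone), the nearest being Thy1 with -1.36 ± 0.27 (adjusted p = 0.0653) and Nkg7 with -1.36 ± 0.46 (adjusted p = 0.271). Thy1 passed with the slide as a block (adjusted p = 0.0456), with the mean of its probes (0.0324) and without WT replicate 3 (0.0344).

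Interferon-stimulated genes were lower as a list (camera, adjusted p = 0.00194), but not with an estimated correlation (adjusted p = 0.575). Values were negative in 12 of 12 members, with a median of -0.34 that turned direction on slide 2 (-0.42 on slide 1 and 0.07 on slide 2). None passed alone (0 with limma, 3 at an unadjusted p under 0.05, 0 adjusted over the list alone). Rsad2 had -1.29 ± 0.62 and Usp18 -1.19 ± 0.48. The alarmin gene Il33 had a log2 fold change of 0.35 ± 0.54 (adjusted p = 0.997, limma, Benjamini-Hochberg), and the probe of Tslp was not well above background on any array. Of 11 alarmin and interleukin genes 0 passed, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera, adjusted p = 0.727), with 0.59 ± 0.57 for Il6. Of 13 chemokines 0 passed, 4 had an unadjusted p under 0.05 and 1 fell when adjusted over the list alone (camera, adjusted p = 0.155, 0.0231 without WT replicate 1 and 0.575 with an estimated correlation). Cxcl2 had 1.5 ± 1.40 and was measured on 1 WT and 2 AhRCA arrays, and Ccl27a, which draws T cells to skin, had -0.97 ± 0.21, with adjusted p of 0.0875 with no block, 0.0157 with the litter pair and 0.0153 with the slide as a block. Of 12 antimicrobial protein genes 1 rose, Lyz1, a lysozyme (1.35 ± 0.12, adjusted p = 0.00546), and 0 fell, while 1 rose and 3 fell when adjusted over the list alone and 2 fell with the litter pair as a block (camera, adjusted p = 0.139, with 0.0464 without WT replicate 2, 0.0249 without AhRCA replicate 1 and 0.575 with an estimated correlation).

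Genes of keratinocyte layers and of cornification mostly did not pass. Of 14 basal keratinocyte genes 1 fell, Krt15, a keratin of basal and follicle stem cells (-0.72 ± 0.13, adjusted p = 0.0460, limma, Benjamini-Hochberg), which missed the threshold with the litter pair as a block (0.0534), under median scaling (0.0838), under quantile normalization (0.0653) and without any 1 array except WT replicate 1 (up to 0.194). Adjusted over the list alone 1 basal gene rose and 1 fell, and with the litter pair as a block 0 passed. The medians were 0.11 for basal genes (camera, adjusted p = 0.139, 0.0344 without WT replicate 1 and 0.622 with an estimated correlation) and 0.02 for 12 spinous genes, of which 0 passed, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera, adjusted p = 0.352); Ovol1 had 0.43 ± 0.27 and Zfp750 0.16 ± 0.10. Of 19 cornified envelope genes 0 passed, 4 had an unadjusted p under 0.05 and 3 fell when adjusted over the list alone, with a median of 0.00 and a mean of -0.25 (camera, adjusted p = 0.139, 0.0237 without WT replicate 1 and 0.629 with an estimated correlation). The lowest were Tchhl1, not well above background on any AhRCA array and at least 2.48-fold lower (adjusted p = 0.0542), and Tchh, a protein of the inner root sheath (-1.17 ± 0.30, adjusted p = 0.138), both past the threshold with the litter pair as a block (0.0114 and 0.0245). Tchhl1 also passed with the slide as a block (0.0446). Of 26 late cornified envelope and small proline-rich genes 1 fell, also when adjusted over the list alone, Sprr4, a cornified envelope precursor (-1.35 ± 0.19, adjusted p = 0.0224, up to 0.1 without 1 array, lost in 5 of 6 such fits); the list's adjusted p was 0.0646 (camera), with 0.0177 under quantile normalization, 0.0191 with normexp background correction, 0.0129 with the mean of a gene's probes, 0.0448 with probes well above background on all 6 arrays, 0.00687 without WT replicate 1 and 0.00445 without AhRCA replicate 1. With an estimated correlation it was 0.618, and the median turned direction between the slides (0.05 on slide 1 and -0.28 on slide 2).

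Of 16 proteases and inhibitors of desquamation 1 fell, also when adjusted over the list alone, the kallikrein Klk6 (-1.26 ± 0.17, adjusted p = 0.0203, limma, Benjamini-Hochberg, up to 0.0921 without 1 array, lost in 5 of 6 such fits). The list's median was -0.22, with -0.10 on slide 1 and -0.42 on slide 2, and stood below the other genes (camera, adjusted p = 0.00434), which it did not with an estimated correlation (adjusted p = 0.575), without WT replicate 3 (0.141) or on slide 1 alone (0.284). Of 17 tight junction and desmosome genes 1 fell, the claudin Cldn3 (-1.16 ± 0.18, adjusted p = 0.0322), and of 11 retinoid metabolism genes 1 fell, the retinaldehyde dehydrogenase Aldh1a3 (-1.23 ± 0.21, adjusted p = 0.0402). Adjusted over the list alone 2 tight junction and 3 retinoid genes fell, with the litter pair as a block 2 and 1, and both lists missed the threshold (camera, adjusted p = 0.0788 each). Both passed with normexp background correction (0.0357 each), and retinoid genes without WT replicate 1 (0.0140), but neither did with an estimated correlation (0.575 each). Cldn3 lost its call without any 1 array except WT replicate 1 (up to 0.117) and Aldh1a3 without any 1 array (up to 0.153), under median scaling (0.0562) and under quantile normalization (0.0507).

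Proliferation, wound and stress programmes showed no gene past the threshold (0 with limma in each list, also adjusted over the list alone). At an unadjusted p under 0.05 there were 1 of 24 cell cycle genes, 2 of 12 wound-type keratinocyte genes, 0 of 7 EGF receptor ligands, 1 of 12 circadian clock genes and 2 of 15 immediate early and heat shock genes. Camera gave these lists adjusted p of 0.155, 0.194, 0.365, 0.154 and 0.0788. Without WT replicate 3 cell cycle genes stood lower and clock genes higher than the other genes (0.0039 and 0.0440), and clock genes also without AhRCA replicate 3 (0.0477) and with array weights (0.0211). On slide 1 alone both passed (0.00516 and 0.00617), and with an estimated correlation neither did (0.782 and 0.629). Their medians turned direction between the slides, from -0.22 on slide 1 to 0.11 on slide 2 for cell cycle genes and from 0.20 to -0.26 for clock genes. With the litter pair as a block the immediate early and heat shock list, which rises with tissue handling, stood above the other genes (adjusted p = 0.0345), with a median of 0.20. With an estimated correlation its adjusted p was 0.688 with the block and 0.575 without it. Mcm2 had -0.30 ± 0.11, Ccne1 -0.26 ± 0.24, Krt6a -1.19 ± 0.50, Krt6b -1.0 ± 0.56, Epgn 0.37 ± 0.30, Areg 0.28 ± 0.29, Hlf 1.0 ± 0.24, Per2 -0.38 ± 0.42, Jun 0.52 ± 0.19 and Ier3 0.45 ± 0.22.

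Markers of other cell types that skin can hold did not pass in the reported fit either. Of 9 fibroblast genes 0 passed (limma), 2 had an unadjusted p under 0.05, 1 rose and 1 fell when adjusted over the list alone, and the median was 0.31, with 0.11 on slide 1 and 0.43 on slide 2 (camera, adjusted p = 0.381); Col3a1 had 0.85 ± 0.68 and Col1a2 -1.19 ± 0.23 (adjusted p = 0.0622). Col1a2 passed with the slide as a block (adjusted p = 0.0464), with normexp background correction (0.0423) and without WT replicate 3 (0.0497). Counts at an unadjusted p under 0.05 were 0 of 9 melanocyte, 1 of 6 skeletal muscle, 2 of 7 Schwann cell and nerve, and 1 of 5 erythroid genes, and camera gave these lists adjusted p of 0.420, 0.821, 0.154 and 0.154. Adjusted over the list alone 1 skeletal muscle and 1 erythroid gene fell, and 0 of the others. Melanocyte genes stood lower as a list without WT replicate 3 (0.00415), with array weights (0.0187) and on slide 1 alone (0.00498), and erythroid genes without WT replicate 1 (0.0237) or AhRCA replicate 1 (0.0287). With an estimated correlation neither list passed (0.802 and 0.575). Their medians turned direction between the slides, from -0.32 on slide 1 to 0.26 on slide 2 for melanocyte genes and from 0.19 to -1.03 for erythroid genes. Mitf had -0.46 ± 0.22, Oca2 -0.42 ± 0.23, Myl1 0.74 ± 0.65, Pmp22 -0.54 ± 0.16, Ngfr -0.39 ± 0.13 and Car1 0.64 ± 0.58. Myh8, with -1.23 ± 0.32, and Slc4a1, with -1.43 ± 0.35 and measured on 1 of 3 AhRCA arrays, passed with the litter pair as a block (adjusted p = 0.0444 and 0.0461). Of mast cell, endothelial and sex-linked genes only 2, 2 and 1 were tested, with 0 passing and 0 at an unadjusted p under 0.05, and of neutrophil genes 0 were well above background on enough arrays. Hdc had -0.64 ± 0.85, Cma1 -0.07 ± 0.19, Plvap -0.12 ± 0.24, Egfl7 0.11 ± 0.24 and Xist -0.86 ± 3.78.

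**Figure D3:**
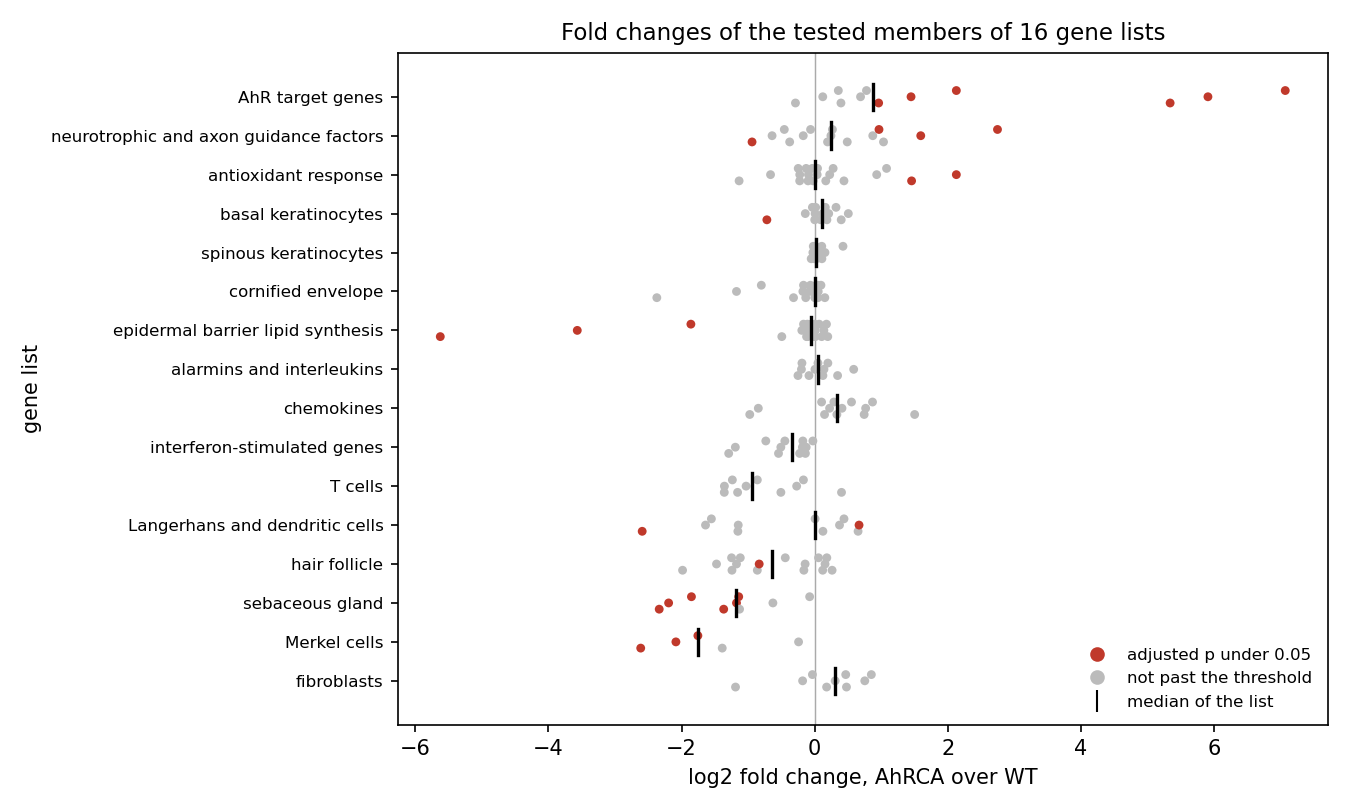
Log2 fold change of AhRCA over WT (horizontal axis) for each tested member of 16 gene lists (vertical axis). Red points passed the threshold, grey points did not, black lines give each list's median, and Fa2h, Cd207, Tchhl1 and Piezo2, not well above background in AhRCA by their tested probes, are drawn at their fitted values. The Merkel cell line lies at the value of Piezo2. The medians are 0.87 for AhR targets and -1.17 for sebaceous gland genes, and 0.11 and 0.02 for basal and spinous keratinocyte genes.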

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

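All tests in this part were chosen after the results were seen. Outside the named genes, 5357 probes with no gene symbol were well above background on enough arrays to be tested. Of these 43 passed an adjusted p of 0.05 with limma, 16 higher in AhRCA than in WT and 27 lower. The 43 are 0.803% and the 16 are 0.299% of these probes. They come from a fit of genes and such probes together, in which 238 of 18181 features changed, 61 of them higher. The shares of 2.18% and 0.53% of genes come from the fit of genes alone, with another adjustment, and cannot be set against them. The gene counts do not use these probes. What they read is not known here, since their sequences were not aligned.

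The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 279 genes, the most of any, so that 1 of 10 splits had as many, and the highest other split gave 3. For gene lists the real split gave 7 and the highest other split 14, and 5 of the 10 splits had as many lists as the real one. The split with 14 lists grouped WT 1 and WT 2 with AhRCA 3; like the real split it parts all 3 litter pairs, as 4 of the 10 do, but it sets WT arrays of slide 1 beside the AhRCA array of slide 2. With slide 1 alone 9 lists passed, and with the slide as a block 7. The smallest unadjusted camera p of the real split was 1.24e-15, for AhR targets, followed by 7.67e-15 for sebaceous gland genes and 4.24e-08 for Merkel cell genes. In the other splits these lists had p of at least 0.00059, 0.000881 and 0.0183. Proteases reached 2.76e-09 and interferon-stimulated genes 2.58e-08 in a split other than the real one. Their p in the real split were larger, 0.000813 and 0.000303. T cell genes also had a smaller p in another split (0.000281) than in the real one (0.00119). Hair follicle genes had 0.000253 in another split and 0.0001645 in the real one.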

How the results depend on the processing

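Slide 1 alone, probes with no symbol and the estimated correlation with the block were chosen after the results were seen; the other settings were planned. The 279 genes kept their sign in every setting in which they were tested. In all 279 the 3 AhRCA arrays lay outside the 3 WT arrays. Fits that only drop, block or weight arrays therefore could not turn their sign. Between 199 and 279 passed again under normexp, quantile normalization, median scaling, the replicate block, the slide block, array weights and the authors' values. The 279 came with array weights, where 2126 genes passed. Fewer passed again with no filter on dim probes (119), on slide 1 alone (97) and without 1 array (61 to 159). The count was between 223 and 322 under normexp (246), quantile (268), median scaling (232), all 6 arrays (223), probe means (300), the robust trend (322) and the authors' values (278). Genes changed, higher and lower numbered 132, 35 and 97 with no filter on dim probes, 2126, 945 and 1181 with array weights, 497, 137 and 360 with the replicate block, 539, 166 and 373 with the slide block, 489, 138 and 351 at an adjusted p under 0.1, and 130, 35 and 95 on slide 1 alone; at least 2-fold, 41 were higher. Leaving out 1 array gave between 62 and 195 genes, 19 to 47 higher and 41 to 148 lower. More tests without the filter and fewer arrays lower the count by construction; the cause was not tested otherwise.

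Lists past the threshold numbered 12 with normexp, 11 with no filter, 3 with fry, 1 with an estimated correlation and 0 with that correlation and the replicate block, and 7 to 15 without 1 array. The 3 with fry were AhR targets (adjusted p = 0.00023), sebaceous gland genes (0.00548) and Merkel cell genes (0.00618). The other called lists did not pass with fry. Its adjusted p was 0.198 for hair follicle and interferon-stimulated genes, 0.202 for proteases and 0.236 for T cell genes. Among named genes and lists the replicate block, which follows the litter pairs, changed no call other than those given with the results. The cause was not tested.

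Normexp with its offset gave log2 fold changes nearer to 0 for these genes: 2.07 for Artn, -2.635 for Elovl3, -1.90 for Soat1, -1.44 for Krt20, 1.22 for Ms4a20, 1.09 for Chst1, -1.475 for Bcan, -1.08 for Steap4, -2.91 for Fa2h and -0.75 for Cd207. An offset does so for dim genes by construction. With no filter on dim probes 20 named genes lost their call and 0 gained one, and with array weights 0 lost and 18 gained one.

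Some results that missed the threshold in the reported fit turned direction. On slide 1 alone the adjusted p in the opposite direction was 0.933 for EGF ligands, 0.681 for cornified envelope, 0.822 for barrier lipid synthesis and 0.767 for fibroblasts, and the log2 fold change was -0.18 for Areg, 0.10 for Hsp90aa1 and 0.18 for Xist. With array weights fibroblasts had 0.878, Areg -0.045, Col3a1 -0.091, Hdc 0.322 and Hsp90aa1 0.213. Skeletal muscle had 0.988 with median scaling, 0.969 with no filter and 0.900 with all 6 arrays, and Plvap 0.063 with normexp. Without 1 array the log2 fold change ranged from -0.01 to 0.959 for Il33, -0.344 to 0.047 for Hsp90aa1, -1.195 to 0.383 for Hdc, -0.178 to 0.133 for Cma1, -0.296 to 0.101 for Plvap, -0.092 to 0.291 for Egfl7 and -3.735 to 3.059 for Xist. The adjusted p of lists ranged from 0.236 to 0.897 for alarmins, 0.0039 to 0.473 for cell cycle, 0.455 to 0.949 for Langerhans cells, 0.00415 to 0.77 for melanocytes, 0.0966 to 0.555 for fibroblasts and 0.245 to 0.949 for skeletal muscle, each with a turn of direction in at least 1 fit. The cause was not tested. Of the 52 named genes past the threshold 25 passed without any 1 array and 27 lost their call at least once. All kept their direction, which was fixed in advance because their groups did not overlap.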

Other observations

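All tests in this part, and all genes and lists named in it, were chosen after the results were seen. Artemin acts through the receptor subunit Gfra3, whose transcript fell by 2.07 on the log2 scale (SE 0.27, adjusted p = 0.0167, limma) and was well above background on 1 of 3 AhRCA arrays, while Artn itself rose. Ramp1, Ramp2 and Ramp3, partners of receptors for calcitonin-family peptides, had -1.66, -1.73 and -0.78 (adjusted p = 0.00850, 0.0138 and 0.0195), and their receptor Calcrl had 0.03 (adjusted p = 0.999). Hsd3b6 was at least 3.45-fold lower (adjusted p = 0.000354) and Akr1c18, well above background on 1 of 3 AhRCA arrays, was lower as well (adjusted p = 0.00787). The ephrin receptors Ephb1 and Ephb2 went in opposite directions, with -1.79 and 1.18 (adjusted p = 0.0167 and 0.0165).

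In hair follicles, structural genes of the shaft and inner root sheath (Krt25, Krt27, Krt31, Krt35, Krt71, Padi3 and Tchh) had a median of -1.24, and 9 patterning genes had 0.06, among which Lgr5 fell (-0.83) and Hoxc13 had -0.44; 0 structural genes passed with limma and 6 did with the litter pair as a block. The 2 sets differed (exact two-sided permutation p = 0.00306, over genes), but they were sorted after their values were seen, so fewer follicle cells in the sampled epidermis and lower expression per cell cannot be told apart. Slide, litter and sex were balanced between the genotypes, and 7 of 7 structural genes were negative on each slide, but on genes chosen this way the count decides nothing about them. Cross-hybridization among keratin-associated protein probes stays open for those genes, since the mean of -1.30 (SE over genes 0.133) comes from structural genes outside that family. Of 31 keratin-associated protein genes 15 fell, 18 with the block, and 29 were negative under every scaling tried, with a median of -2.09 that was -1.335 with normexp. The stage of the follicles was not measured here.

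Among immune genes, Cd207 and the class II genes H2-Aa, H2-Ab1 and Cd74 had a mean of -1.73 and the other Langerhans and dendritic cell genes 0.16 (exact two-sided permutation p = 0.00303, over genes). Mfge8, one of the others, had -1.15 (adjusted p = 0.0677, and 0.0142 with the litter pair as a block). The 2 sets were divided after their values were seen, so fewer Langerhans cells and lower expression per cell cannot be told apart. Of 15 macrophage genes, 1 of them also in a fixed list, 5 rose (9 with the block), among them Trem2 (1.42) and C1qa (0.86), and 15 of 15 were positive on both slides and under every scaling, with a median of 0.834 that was 0.525 with normexp. Dermis carried over into AhRCA samples would raise fibroblast genes as much. On slide 1 the macrophage genes averaged 0.82. Col1a1, Col3a1, Lum and Thbs2 were the 4 fixed fibroblast markers with WT means as low and well above background on all 6 arrays. They averaged 0.04 on slide 1 (0.388 at 2 standard errors over genes above the mean). This does not decide about carry-over there, since the macrophage genes were gathered after some were seen to change. Col3a1 also stood higher on the WT arrays of slide 1 (-1.56 and -1.30) than on that of slide 2 (-3.84). Twist2 had a WT mean lower still (-5.51). It was left out of the means by slide because it was well above background on only 1 WT and 2 AhRCA arrays. Its log2 fold change was 0.11 on slide 1 and 2.04 on slide 2. On slide 2 the macrophage and fibroblast means were 0.90 and 1.13 (2.064 at 2 standard errors). With 1 pair, carry-over and a rise within the epidermis cannot be told apart there either. Slide, litter and sex were balanced between the genotypes; the smallest of the 4 medians by slide, 0.772, lay on the side of the pattern, but on genes gathered after some were seen to change it decides nothing about them. More macrophages and a changed state of resident cells were not tested against each other.

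Sebaceous gland genes kept a median of -1.14 or lower under 75th percentile, median and quantile scaling (nearest to 0, -1.14 with median scaling). The choice among these scalings therefore does not account for the fall. The median of all tested genes was 0.0013, 0.0342 and -0.0014 under them, so they differed too little to test scaling further. On the 2 slides the list's median nearest to 0 was also -1.14, so the fall was not limited to 1 slide. Slide, litter and sex were balanced between the genotypes, and the values by slide decide nothing further about them. Fewer gland cells and lower expression per cell were not tested against each other, and either may underlie the fall.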
